A study of Mus musculus with 11 samples.

How the data were processed

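The series holds 11 ChIP-seq libraries from glands of the mouse stomach, 8 made with an antibody to acetylated lysine 27 of histone H3 (H3K27ac) and 3 labelled as trimethylated lysine 4 (H3K4me3). Per the labels' protocols, fixed epithelial pellets were pooled until enough material was in hand, sonicated and immunoprecipitated, and single-end libraries were made with a ThruPLEX kit. The protocol names an H3K27ac antibody for every library, and the H3K4me3 antibody is not given in the sources used here. Since pellets were pooled, whether the libraries of a group came from different animals is not known, and p-values measure only the spread between these libraries.

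Libraries were grouped by the genotype in the labels: wild type, Atp4bCre with Rosa26NICD (NICD), NICD with 1 floxed Arid1a allele (1-allele) and NICD with 2 floxed Arid1a alleles (2-allele). Each H3K27ac group held 2 libraries and each H3K4me3 group 1. The labels of the Arid1a-floxed H3K4me3 library disagree, with 1 allele in its title and 2 in its genotype, so it was kept as a group of its own with the allele number open.

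Per the submitters' processing notes, reads were aligned with Bowtie2 to GRCm38 (mm10) and peaks were called with MACS2. Per the file headers, 9 lists came from MACS 2.0.10.20131216, run on each library alone with no control, duplicate reads removed, a q-value threshold of 0.05 and a local background of up to 10 kb. The headers also give an effective genome size of 2.7 Gb under the setting for human, although the reads were from mouse. Each peak in these deposited lists has a summit pileup signal, a −log10 p-value and −log10 q-value, and a fold enrichment over the background of the same library. These scores are the authors' and were used only to rank or filter peaks inside a list. Both 2-allele lists hold positions only, with no header or score, so how they were called and how many reads lay behind them is not given in the sources used here. Their order in the file behaved as an order of strength: of the first 1000 regions of replicate 1, 95.6% overlapped a peak of 1-allele replicate 2, against 17.5% of those after the first 8000. A library called without a control against a local background can miss wide, strong domains, and a missing peak is not a missing mark.

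Depth is given by the headers. Tags after duplicate removal numbered 18.26 M and 17.02 M in wild type, 13.91 M and 7.96 M in NICD, and 16.62 M and 9.76 M in the 1-allele libraries. The H3K4me3 libraries held 20.81 M (wild type), 11.75 M (NICD) and 13.64 M (Arid1a-floxed). NICD replicate 2 stood apart with a redundant rate of 0.52.

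Peaks on chromosomes 1 to 19, X and Y were kept. Regions were called shared when they overlapped by at least 1 bp. The gene table used (GRCm38, 21887 protein-coding genes) gives no strand, so the plan to measure from annotated transcription start sites was altered: where an H3K4me3 peak of any library lay within 1 kb of a single end of a gene, that end was taken as its start (12599 genes), and for the other 9288 genes both ends were kept. H3K27ac lay at the chosen end of 25.6% to 81.0% of the 12599 genes, depending on the library, and at the other end of 0.0317% to 2.33%. The other end was set aside for lacking H3K4me3, whose peaks many H3K27ac peaks overlap, so these shares are no independent check of the choice. A promoter peak is a peak within 1 kb of a gene start and a distal region is one with no gene start within 1 kb. Neighbouring genes can share a promoter peak.

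The comparisons were NICD against wild type, 1-allele against NICD, 2-allele against NICD, and 2-allele against 1-allele. Values per library were tested by an exact permutation test of the sum of squares between groups over the 105 ways to pair 8 libraries (15 for 6 libraries). Pairs of groups were compared by a two-sided exact permutation test, which cannot go below 0.333 with 2 libraries against 2. Benjamini-Hochberg adjustment ran over 6 values per library and over 27 gene lists. NICD regions were merged regions called in both NICD libraries, and their strength was the mean percentile of the peak within its list. Distal and promoter regions were compared inside 10 classes of that strength. Regions and genes were counted as separating 2 groups when called in both libraries of one and neither of the other, with the counts from the other ways to pair the same 4 libraries beside them.

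Before the data were examined, 27 gene lists were fixed, with 585 of 592 names matched. They cover parietal, chief, mucous neck, surface pit, endocrine, isthmus and stem cells, gastric transcription factors, intestinal, metaplasia (SPEM) and squamous genes, the Notch and p53 pathways, apoptosis, cell cycle, Wnt targets, SWI/SNF, Polycomb and acetylation, epithelial-mesenchymal transition, tumour suppressors and oncogenes, inflammatory signalling, haematopoietic, fibroblast and muscle, endothelial, housekeeping and silent genes, endoplasmic reticulum stress and mitochondrial energy. For each list the log2 odds of a promoter peak against all other genes of the same library were computed, with 0.5 added to each cell. The share of a list's NICD promoters kept in another group was set against 10000 random gene sets of matched NICD strength. Genes named in the text were, per comparison, up to 8 on each side ranked by mean percentile, up to 4 members of each list described, and Arid1a, Notch1, Atp4b and Hes1. Predicted genes were passed over among the 8, and some genes that this rule names are not reported here.

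The calculations were tested on simulated lists drawn from the 41405 peaks of NICD replicate 1. A loss of 20 points at distal regions put into the 2-allele group was recovered as −20.0 points over 20 draws, and 0.14 points came back with no loss put in. In the exact test over the 4 groups, a cell cycle list lowered in wild type reached an unadjusted p below 0.05 in 18 of 20 draws and an adjusted one in 0. It did so in 6 of 20 draws with nothing lowered, and in 0 of 20 when every group was also drawn at the same rate. Both libraries of a simulated group were drawn at one rate from the same peaks, whereas the NICD lists held 41405 and 25442 peaks. The simulation therefore lacks such spread between libraries, and its recovery and detection can be better than in these data. With 27 lists and a smallest exact p of 0.00952, a list alone at that p has an adjusted value of 0.257. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only.

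Alternatives fixed beforehand were a −log10 q of at least 5, equal numbers of peaks per list (5165), autosomes only, a promoter window of 2.5 kb, an overlap of 50% of the region, no matching or matching on width, odds against housekeeping genes, each library left out, and the replicate number as a block. Added after seeing the data were equal numbers that include the 2-allele lists by file order (5165 peaks each, or 14373 without the 1-allele lists), the same 2 lengths for wild type and 2-allele alone, 18360 peaks for wild type and NICD alone, either gene end as the start, promoters taken from H3K4me3 regions, and peaks reduced to 200 bp. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.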

Results

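Stomach glands were profiled for H3K27ac, a histone mark of active promoters and enhancers, and for H3K4me3, a mark of promoters. The mice were wild type or carried Atp4bCre, a Cre recombinase under control of a parietal cell gene, together with Rosa26NICD, which supplies the intracellular, active part of Notch. On the NICD background, Arid1a, which encodes a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex, was floxed on 1 or on 2 alleles. The title of the series names the dosage of Arid1a in gastric tumours as its subject. H3K27ac was measured in 2 libraries of each of the 4 groups and H3K4me3 in 1 library of wild type, NICD and Arid1a-floxed glands. Tags after duplicate removal ranged from 7.96 M to 18.26 M over the H3K27ac libraries with a stated depth, and the depth of the 2-allele libraries was unknown.

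The H3K27ac lists held 19475 ± 1577 peaks in wild type, 33424 ± 11288 in NICD, 6384 ± 1723 in the 1-allele group and 14868 ± 699 in the 2-allele group (SD, n = 2 each). Peaks per library differed among the 4 groups by more than the spread inside them (exact permutation p = 0.00952, the smallest the design allows, adjusted p = 0.0286, n = 2 per group). Covered length, with means of 5.97, 15.2, 2.14 and 7.09 Mb in the same order, gave the same exact p and adjusted p. The 2-allele lists also differed in shape, with median peak widths of 409 and 410 bp and maxima of 1773 and 1758 bp. The other H3K27ac lists had medians of 240 to 396 bp and maxima of 3789 to 3875 bp. Covered length therefore cannot separate the 2-allele genotype from the unstated way those lists were made. Tags did not follow list length, since the 1-allele library with 16.62 M tags had 5165 peaks and the NICD library with 7.96 M had 25442.

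**Figure D1:**
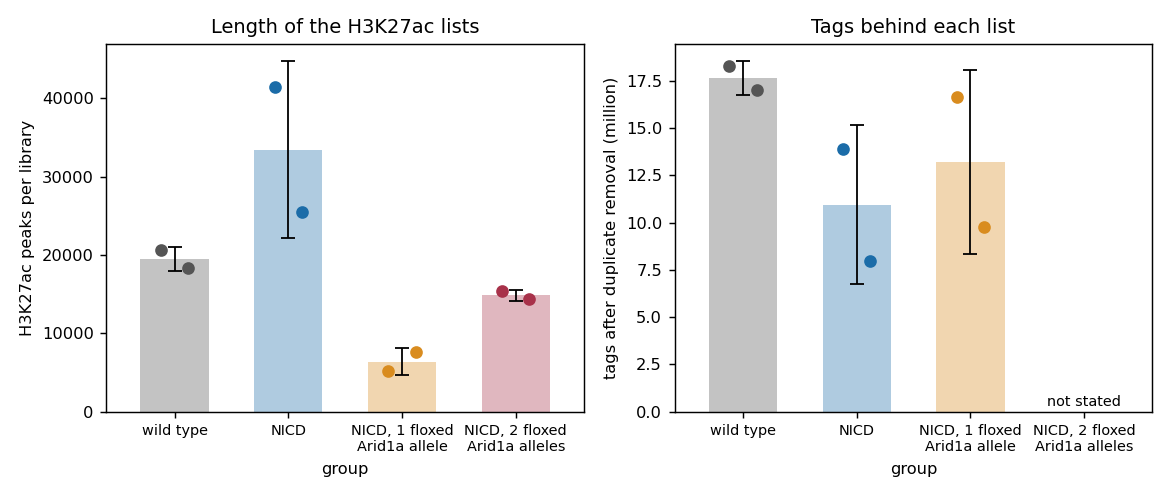
H3K27ac peaks per library (left) and tags after duplicate removal in M (right) for the 4 groups, with libraries as points, means as bars and SD as whiskers (n = 2). Both 1-allele lists, with 5165 and 7602 peaks, were shorter than all other lists, while their libraries held 16.62 M and 9.76 M tags.

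The genes named by the design were read in every library. Arid1a (chromosome 4, 133679008 to 133756769, GRCm38) carried an H3K27ac promoter peak in both wild-type, both NICD and both 2-allele libraries and in neither 1-allele library. A peak at the Arid1a promoter does not test whether the floxed part was removed. Notch1 (chromosome 2, 26457902 to 26503822) showed the same pattern. Atp4b (chromosome 8, 13386209 to 13396778), which encodes the beta subunit of the gastric proton pump, was called in both wild-type libraries, 1-allele replicate 1 and no NICD or 2-allele library. Hes1 (chromosome 16, 30065357 to 30067796), a classical Notch target, was called in both wild-type libraries and NICD replicate 1 alone.

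NICD against wild type asks what active Notch does to the gland's chromatin. Of 30 cell cycle genes, 24 and 17 carried a peak in the NICD libraries against 10 and 10 in wild type. Aurkb, a mitotic kinase, Ccnb1 and Ccnb2, the B-type cyclins, and Mcm3, part of the replicative helicase, were among 8 members called in both NICD and no wild-type library, and no member had the opposite pattern. Parietal cell genes leaned the other way, with 6 and 6 of 16 called in NICD and 8 and 8 in wild type. Hrh2, the histamine receptor that drives acid secretion, and Atp4b were called in both wild-type and neither NICD library. Of 30 Notch pathway genes, 25 and 21 were called in NICD and 16 and 18 in wild type, and Hey2 and Heyl, hairy-related repressors, and Maml2 and Maml3, Notch co-activators, were called in both NICD and no wild-type library, although Maml2 and Maml3 did not keep this pattern with a promoter window of 2.5 kb. None of the genes named in this paragraph as separating NICD from wild type did so in lists of 5165 peaks.

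The log2 odds of a cell cycle promoter peak were 1.15 ± 0.86 in NICD and −0.49 ± 0.09 in wild type (SD, n = 2 each), and over the 4 groups the exact permutation p was 0.0190 (adjusted p = 0.103, n = 2 per group). With 14373 peaks per list the cell cycle counts were 14 and 11 in NICD and 6 and 8 in wild type, and each of the 6 libraries then called 6 parietal genes, whereas with 18360 peaks per list parietal genes stayed at 6 and 6 in NICD against 8 and 8 in wild type. With 5165 peaks per list the cell cycle difference turned to −0.16, from at most 2 members called in a library. For parietal genes the odds differed by −1.17 (exact permutation p = 0.143 over the 4 groups, adjusted 0.321, n = 2 per group). For Notch pathway genes they differed by 0.85 (exact permutation p = 0.105 over the 4 groups, adjusted 0.281, n = 2 per group). With 18360 peaks per list the Notch counts were 19 and 18 in NICD against 16 and 18 in wild type. With 14373 they were 17 and 17 against 15 and 16. Leaving out 1 library moved the Notch difference between 0.49 and 1.20 and the cell cycle difference between 1.03 and 2.24.

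Members of other lists also separated these groups. Bax, a p53 target that promotes cell death, was called in both NICD and both 2-allele libraries and no wild-type library, but did not separate NICD from wild type when either gene end was taken as the start. Pdx1, a transcription factor of the antrum and duodenum, Gata6 and Elf3 were called in both NICD and no wild-type library, a pattern that Gata6 and Elf3 did not keep at 2.5 kb. Blood cell genes were called in 6 and 2 of 30 cases in NICD and 1 and 0 in wild type, a count of 1 and 2 against 1 and 0 with 18360 peaks per list, with Ptprc, the pan-leukocyte CD45 gene, called in both NICD libraries. The patterns of Bax, Pdx1, Gata6, Elf3 and Ptprc did not hold in lists of 5165 peaks.

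Across the genome, 5933 regions were called in both NICD and neither wild-type library and 248 in both wild-type and neither NICD library, against at most 1350 for the other ways to pair these 4 libraries. Of the 5933, 76.0% were distal, against 48.8% of all regions called in both NICD libraries, shares that are not matched on strength. Protein-coding genes with such promoter peaks numbered 841 and 23. The strongest on the NICD side included Nudcd3, Nup210l, Gtf2a1, Anapc5, Csrnp1, Erfe and Pemt, and of these Erfe and Pemt kept the pattern with a 2.5 kb window. On the wild-type side they were Hrh2, Hspa12b, Ank1, Adgrf2, Gpm6a, Palm3, Hamp2 and Prok2, and all but Hspa12b kept it. With 5165 peaks per list the region counts were 474 and 394, and the NICD pattern of these genes held but the wild-type pattern did not. A shorter list drops its weakest peaks and adds none, so genes chosen for strong NICD peaks keep this pattern by construction. Without NICD replicate 2 the NICD count was 22274 regions and 1720 genes, without wild-type replicate 2 the wild-type count was 2027 regions, and without NICD replicate 1 it was 166 genes.

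The 1-allele against NICD comparison asks what loss of a single Arid1a allele adds to active Notch. Most NICD regions had no peak: of 21535 regions called in both NICD libraries, 26.3% ± 7.4 were called in the 1-allele libraries (SD, n = 2), against 62.2% ± 1.5 in wild type (SD, n = 2). Leaving out 1 library at a time moved these means between 14.1% and 31.6% and between 37.4% and 63.3%. The missing promoters included regulators of the cell cycle (Aurka, Pcna, Mcm6, Mcm4), of apoptosis (Birc5, Fadd, Tnfrsf1a, Diablo) and of the p53 response (Phlda3, Ddb2, Trp53i11, Sesn2). Gastric transcription factors Sox2, Sox21, Ehf and Pdx1, Notch genes Notch1, Notch4, Hes7 and Hey2, and Cdh1, the gene for E-cadherin, were also called in both NICD and neither 1-allele library. Housekeeping promoters were missing too, with 13 and 19 of 30 called against 28 and 26 in NICD, and Psmb4, Gusb and Rps18 were called in neither 1-allele library. Birc5, Cdh1 and Psmb4 kept the pattern in lists of 5165 peaks and the other genes of this paragraph did not. A shorter list adds no peak, so a promoter missing from the full 1-allele lists stays missing. Keeping the pattern therefore reflects only the strength of the NICD peaks.

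Regions called in both NICD and neither 1-allele library numbered 13334, of which 62.1% were distal, and 33 had the opposite pattern (at most 115 for the other pairings). The matching gene counts were 4098 and 2. Of all regions called in both NICD libraries 48.8% were distal, but these shares are not matched on strength. At equal NICD strength, distal and promoter regions differed by 1.38 and −5.45 points in the 1-allele libraries, so the 62.1% does not show a loss particular to distal regions. The strongest missing promoters were Golph3, Tmem167b, Nudcd3, Asic1, Zkscan8, Nup210l, Leng8 and Fiz1, of which Tmem167b, Zkscan8 and Fiz1 kept the pattern at 2.5 kb. Sspn was the only ranked gene called in both 1-allele and neither NICD library, and it did not keep the pattern at 2.5 kb. With 5165 peaks per list the counts of regions were 575 missing and 364 with the opposite pattern, and these 8 missing promoters, but not Sspn, kept their pattern. The 8 were chosen for strong NICD peaks and a shorter list adds no peak, so their pattern holds by construction. Without 1-allele replicate 2 the missing genes numbered 6723 and the opposite regions 171, without 1-allele replicate 1 the opposite genes numbered 13, and without NICD replicate 2 the missing regions numbered 32563.

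Relative to all other genes, the log2 odds in the 1-allele group differed from NICD by −2.44 for cell cycle genes, −1.01 for p53 genes, −0.92 for gastric transcription factors and −0.85 for Notch genes. For apoptosis genes the difference was −1.71 (exact permutation p = 0.00952 over the 4 groups, adjusted p = 0.103, n = 2 per group). Apoptosis genes were called in 6 and 10 of 24 cases, against 22 and 20 in NICD. Inflammatory signalling genes differed by 0.74, with 8 and 9 of 26 called against 15 and 13. Over the 4 groups the exact permutation p for this list was 0.0190 (adjusted p = 0.103, n = 2 per group). Relb, Cxcl5, Socs3 and Ifit3 were called in both NICD and neither 1-allele library. Relb alone of these 4 kept the pattern with 5165 peaks per list. A shorter list adds no peak, so this reflects only the strength of its NICD peaks. With 5165 peaks per list the differences for cell cycle, p53, gastric transcription factor, Notch and inflammatory genes changed sign, to 1.13, 0.026, 0.54, 0.074 and −0.060. The share of a list's NICD promoters kept in the 1-allele libraries, against the median of random sets of equal NICD strength, was 14.7% against 14.7% for cell cycle (percentile 50.8), 45.2% against 45.2% for Notch (percentile 52.3) and 40.0% against 42.5% for apoptosis genes (percentile 31.5). For p53 genes it was 53.8% against 48.1% (percentile 80.2), for gastric transcription factors 34.6% against 26.9% (percentile 84.1) and for inflammatory genes 65.4% against 57.7% (percentile 88.8).

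Surface pit cells are the mucus-secreting cells at the gland's mouth. Of the 14 genes of their list, 6 and 3 were called in the 1-allele libraries against 13 and 8 in NICD, a log2 odds difference of −0.88. Of 8 of their promoters that were called in both NICD libraries, 50.0% were called in the 1-allele libraries, whereas random sets of equal NICD strength kept a median of 12.5% (percentile 99.975 of 10000). This is a description of these libraries and 66 such percentiles were computed, of which 4 lay in the outer 5%. The other 3 were cell cycle genes in wild type (percentile 0.635) and, in the 2-allele libraries, inflammatory genes (percentile 1.45) and tumour suppressors and oncogenes (percentile 98.5).

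**Figure D2:**
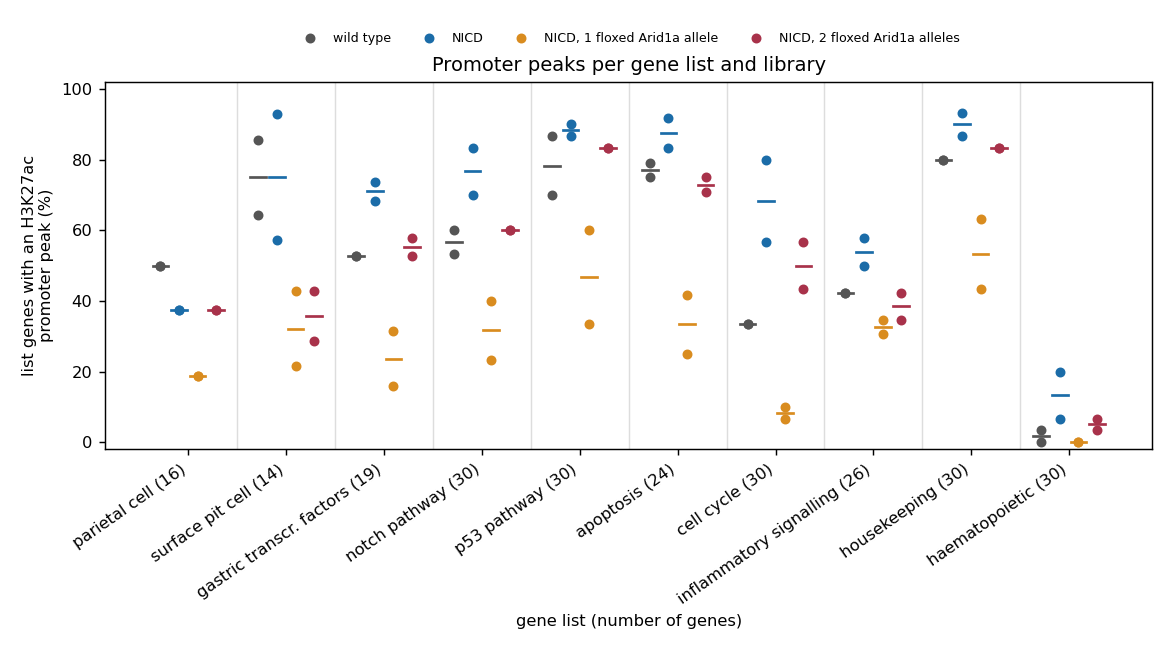
Share of each gene list with an H3K27ac promoter peak (vertical axis, percent) for 10 lists (horizontal axis, number of genes in brackets), with libraries as points and group means as short lines (n = 2). Cell cycle genes lay at 33.3% in wild type, 68.3% in NICD, 8.33% in the 1-allele group and 50.0% in the 2-allele group.

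The 2-allele against NICD comparison asks the same of both alleles. Promoters were mostly called in both groups: 80.9% ± 2.6 of promoter NICD regions had a peak in the 2-allele libraries, against 35.6% ± 2.4 of distal ones (SD, n = 2). In wild type these shares were 78.3% ± 2.8 and 45.4% ± 0.2 (SD, n = 2), so most of this contrast was also there without floxed Arid1a. Neither pair of shares is matched on strength. Of 30 p53 pathway genes, 25 were called in all 4 libraries, and Trp53i11 was the only member in both NICD and neither 2-allele library. Of 29 SWI/SNF genes, 20 were called in all 4 libraries and none separated the groups. Heyl and Dll4 of the Notch list, Ccnb1, Cdc20 and Mybl2 of the cell cycle list, Pdx1 and Elf3 of the gastric transcription factors, and Bhlha15 and Clps of the chief cell list were called in both NICD and neither 2-allele library. Ccne1, the gene for cyclin E1, had the opposite pattern. None of these genes kept its pattern in lists of 5165 peaks.

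At equal strength in NICD, distal regions were called less often than promoters in the 2-allele libraries, with gaps (distal minus promoter) of −21.8 and −20.5 points, and in wild type, with −11.8 and −6.30 points, while the 1-allele libraries gave 1.38 and −5.45 points. The mean gap was −21.2 ± 1.0 points in the 2-allele group, −9.1 ± 3.9 in wild type and −2.0 ± 4.8 in the 1-allele group (SD, n = 2 each). The exact permutation p over these 3 groups was 0.0667 (adjusted p = 0.0667, n = 2 per group), the smallest that 6 libraries allow, so the design cannot reach 0.05. When promoters were taken from H3K4me3 regions instead of gene ends, the gap was −27.0 and −26.0 points in the 2-allele and −22.7 and −18.1 points in the wild-type libraries. In lists of 5165 peaks it was −11.3 and −8.99 points in the 2-allele and −5.24 and −1.14 points in the wild-type libraries.

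**Figure D3:**
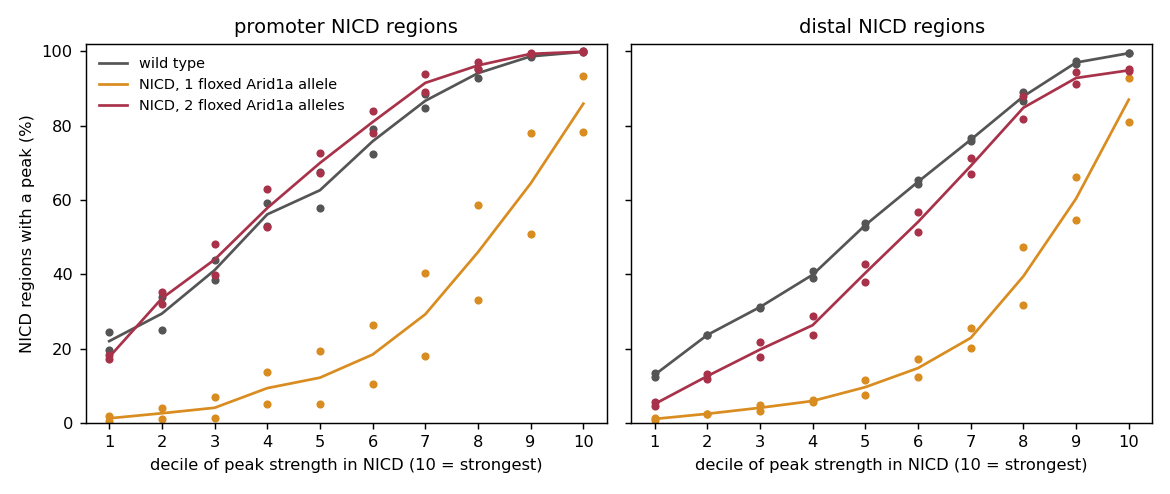
Share of NICD regions with a peak in each library (vertical axis, percent) by decile of peak strength in NICD (horizontal axis, 10 is strongest), for promoter (left) and distal (right) regions, with libraries as points and group means as lines (n = 2). In decile 5, 72.7% and 67.2% of promoters and 42.8% and 37.9% of distal regions had a peak in the 2-allele libraries, against 67.5% and 57.7% of promoters and 53.7% and 52.8% of distal regions in wild type.

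Regions called in both NICD and neither 2-allele library numbered 7066, of which 81.2% were distal, and 40 had the opposite pattern (at most 630 for the other pairings). The gene counts were 821 and 6. Of all regions called in both NICD libraries 48.8% were distal, and these shares are not matched on strength. The strongest missing promoters included Nudcd3, Nup210l, Fam221b, Tmem8b, Sh2b1, Synpo and Grk3, and of these Fam221b, Tmem8b (a shared promoter), Synpo and Grk3 kept the pattern at 2.5 kb. Zfp451, Irf2bp1, Ank1, Lrp2 and Ccne1 were called in both 2-allele and neither NICD library, of which Ank1, Lrp2 and Ccne1 kept the pattern. In lists of 5165 peaks Nudcd3, Nup210l, Fam221b, Tmem8b, Sh2b1 and Grk3 were still missing, and the other genes of this paragraph did not keep their pattern. Genes chosen for strong NICD peaks tend to stay missing by construction, since a shorter list adds no peak. With 14373 peaks per list, 941 regions were missing and 592 had the opposite pattern, and without NICD replicate 2 the missing regions numbered 24964 and the missing genes 1839. Without NICD replicate 1 the opposite pattern held for 423 regions and 0.480% of the 21887 protein-coding genes, against 0.0274% with all libraries.

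The log2 odds of the 2-allele group differed from NICD by −0.67 for cell cycle genes (17 and 13 called), −0.65 for Notch genes (18 and 18) and −0.08 for p53 genes (25 and 25), the last of which was 0.11 with a 2.5 kb window. Surface pit genes differed by −2.11, with 6 and 4 of 14 called against 13 and 8 in NICD (exact permutation p = 0.410 over the 4 groups, adjusted 0.614, n = 2 per group), and Psca and Vsig1 were called in both NICD and neither 2-allele library. With 14373 peaks per list the cell cycle difference was 0.076, from 13 and 13 against 14 and 11, and with 5165 peaks the cell cycle difference was reversed to 1.15, the surface pit difference was 0.79 and neither Psca nor Vsig1 kept its pattern. Leaving out 1 library moved the cell cycle difference between −1.27 and −0.063, that of Notch genes between −1.01 and −0.30 and that of surface pit genes between −3.34 and −0.88. Against random sets of equal NICD strength, the share kept was 70.6% against a median of 64.7% for cell cycle genes (percentile 79.6), 83.3% against 83.3% for Notch genes (percentile 51.0) and 56.2% against 62.5% for surface pit genes (percentile 26.3).

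The 2-allele against 1-allele comparison sets the 2 allele numbers side by side. Of the fixed lists, 8 of 30 cell cycle, 7 of 24 apoptosis, 6 of 30 p53 and 4 of 30 housekeeping genes were called in both 2-allele and neither 1-allele library. Among them were Cdk4, Pcna, Aurka and Mcm4 of the cell cycle list, Fadd, Tnfrsf1a and Birc5 of the apoptosis list, and Phlda3, Sesn2, Pidd1 and Ddb2 of the p53 list. Trp53 itself, Cdh1, Akt1 and Hras, the stem and progenitor factors Sox9 and Sox2, and the BAF subunit genes Arid1a, Arid2, Dpf2 and Smarcc1 showed this pattern, although that of Arid2 did not hold at 2.5 kb. In all, 4194 regions were called in both 2-allele and neither 1-allele library and 169 the other way (at most 245 for the other pairings), and 33.0% of the 4194 were distal. The gene counts were 2621 and 8. Of all 2-allele peaks 66.7% lay at promoters, so the distal share of the 4194 was near that of the whole lists. In lists of 5165 peaks, cell cycle genes were called in 2 and 2 cases in the 2-allele and 2 and 1 in the 1-allele libraries, and of the genes named in this paragraph Tnfrsf1a alone kept the pattern. Since a shorter list adds no peak, that reflects only the strength of its 2-allele peaks.

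The strongest genes on the 2-allele side were Bag1 and Chmp5 (a shared promoter), Asic1, Ccdc62, Stpg2, Tmem167b, Map2k2 and Med30, and all but Asic1 kept the pattern at 2.5 kb. Synpo, Sspn, Kbtbd12, Elapor2, Sntb1, Frmd4b and Hs3st3a1 were called in both 1-allele and neither 2-allele library and all 7 kept it. The region counts were 622 and 417 in lists of 5165 peaks, where the 8 genes of the 2-allele side kept their pattern and, of the other 7, Kbtbd12 did. The 8 were chosen for strong 2-allele peaks and a shorter list adds no peak, so their pattern holds by construction. For the same reason Kbtbd12 could not appear in the 2-allele lists, and its pattern reflects only the strength of its 1-allele peaks. Without 1-allele replicate 2 the 2-allele side held 6969 regions and 5068 genes, and without 1-allele replicate 1 the other side held 523 regions and 81 genes. The 2-allele lists were made in a way that the sources used here do not give, so list making and allele number cannot be separated in this comparison. The 2-allele libraries are also numbered apart from all others in the series. Any difference in their preparation or sequencing cannot be separated from allele number either, here or against NICD and wild type.

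Losses with 1 and with 2 floxed alleles overlapped. Of 21535 NICD regions, 13697 had no peak in either 1-allele library, 7086 none in either 2-allele library and 6656 none in any of the 4. Independent losses would share 4507, and losses independent inside each decile of NICD strength 6364.5 (simulated range 6218 to 6593 over 1000 draws). Both comparisons use the same NICD libraries, and part of the excess may come from them. In lists of 5165 peaks 125 losses were shared, and without NICD replicate 2 the number was 24464.

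The share of peaks at promoters was 55.3% ± 0.6 in wild type, 41.6% ± 10.23 in NICD, 68.7% ± 4.6 in the 1-allele group and 66.7% ± 0.9 in the 2-allele group (SD, n = 2 each, exact permutation p = 0.0286, adjusted p = 0.0429). Genes with a promoter peak numbered 9166 ± 337, 10946 ± 884, 4582 ± 1493 and 9157 ± 220 in that order (SD, n = 2 each, exact permutation p = 0.0286, adjusted p = 0.0429). With the replicate number as a block, the exact permutation p was 0.0833 for promoter share and for promoter genes. In lists of 5165 peaks the promoter share differed by 3.81 points (NICD minus wild type) and −8.28 points (1-allele minus NICD), the reverse of the full lists. The 2-allele minus 1-allele share (11.2 points) and the 2-allele minus NICD number of genes (143.5) were reversed in these lists too. The exact permutation p of the promoter share was 0.0762 without 1-allele replicate 2, where the 2-allele minus 1-allele share was 1.27 points, 0.0667 without replicate 1 or 2 of the 2-allele group and 0.0571 without replicate 1 or 2 of wild type. Retention of NICD regions over the 3 other groups had an exact permutation p of 0.0667 (adjusted p = 0.0667, n = 2 per group), again the smallest possible.

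Of the 27 lists, 7 had an unadjusted exact permutation p below 0.05 and 0 an adjusted one (n = 2 per group). Besides apoptosis, cell cycle and inflammatory signalling, these were endothelial genes (p = 0.00952, at most 3 of 16 called), housekeeping genes (p = 0.0190), gastric transcription factors (p = 0.0286, adjusted 0.129) and Wnt targets (p = 0.0476, adjusted 0.184), all exact. Unequal list lengths alone can give such a p. In the simulation with nothing lowered, the cell cycle list fell below 0.05 in 6 of 20 draws, and in 0 of 20 at equal rates. The exact p was 0.0667 for chief cell genes, 0.105 for tumour suppressors and oncogenes, 0.114 for endoplasmic reticulum stress, 0.162 for metaplasia, 0.229 for fibroblast and muscle, 0.257 for haematopoietic and 0.295 for silent genes. It was 0.362 for the p53 pathway, 0.457 for SWI/SNF, 0.514 for mucous neck, 0.562 for epithelial-mesenchymal transition, 0.590 for isthmus and stem, 0.600 for mitochondrial energy and 0.638 for intestinal genes. For squamous and for Polycomb and acetylation genes the exact p was 0.676, and for endocrine genes 0.886.

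H3K4me3 was measured in 1 library per group, with no replicate check and no test. Promoters of 10370 genes carried a peak in wild type (47.4%, exact binomial interval 46.7% to 48.0%), 13904 in NICD (63.5%, 62.9% to 64.2%) and 4264 in the Arid1a-floxed library (19.5%, 18.96% to 20.0%). The H3K4me3 lists held 17558, 39420 and 5175 peaks in that order, so the gene counts rank as list length does. At promoters lay 72.2%, 41.6% and 75.4% of these peaks. Nearly all genes of the floxed list, 4262, also had a peak in NICD, and 10354 of the 10370 wild-type genes did. Cell cycle promoters had an H3K4me3 peak in 25 of 30 cases in wild type, 29 in NICD and 6 in the floxed library. Aurkb, Ccnb1, Ccnb2, Mcm3 and Hrh2 carried H3K4me3 in wild type and NICD alike, and Atp4b in NICD and the floxed library. Of H3K27ac peaks, 58.8% ± 1.4 in wild type and 68.7% ± 12.02 in NICD overlapped H3K4me3 of the same genotype (SD, n = 2 each). Against the floxed H3K4me3 list, whose allele number is disputed, the overlap was 38.7% ± 2.5 for the 1-allele and 27.4% ± 0.7 for the 2-allele group (SD, n = 2 each), an order that turned round to 41.6% and 47.4% in lists of 5165 peaks. The 5175 peaks of the floxed list limit these shares. Against the longer NICD H3K4me3 list, 92.2% and 95.3% of 1-allele and 91.0% and 92.0% of 2-allele peaks overlapped. Against the wild-type list the shares were 83.7% and 84.3%, and 69.3% and 71.3%. The low values therefore do not show that the 2 marks part with floxed Arid1a.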

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

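All tests of explanations in this part were chosen after the data had been seen; the bounds called set beforehand were written down before the tests they belong to were run, and the values with lists of 5165 peaks were added after those results. No group held the 4 libraries needed to test for a library apart from its group, and no library had more peaks on the mitochondrial genome than the wild-type libraries of its mark, so none of the 3 patterns weighed here was picked by such a rule.

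The H3K27ac lists with 1 floxed Arid1a allele were the shortest. Fewer unique tags are argued against, since the 1-allele libraries held 1.21 times the mean tags of the NICD libraries. Weak enrichment at every kind of gene stays open: the 1-allele libraries called 48.1% and 70.4% of the NICD mean number of housekeeping promoters, but the NICD lists themselves called 55.6% and 66.7% of it with 5165 peaks. Any cause of a short list could give such values, so they do not part weak immunoprecipitation from a wide loss of acetylation. A loss that grows with the number of floxed alleles cannot be told apart from other causes, since the shorter 2-allele list was 1.89 times as long as the longer 1-allele list but was made in an unstated way.

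Distal NICD regions were missed more than promoters of equal strength in the 2-allele libraries. Whether different list lengths are the cause depends on the length chosen. With 14373 peaks in each wild-type and 2-allele list, the nearer 2-allele library differed from the lower wild-type library by −10.9 points. That was past the 5 points set beforehand by more than the wild-type SD of 2.88, but 14373 is the full length of 2-allele replicate 2. At 5165 peaks the gaps of both groups shrank. The difference was then −4.05 points (−3.75 with every list at 5165), inside the 5 points, so list length remains open. With peaks of 200 bp the difference was −5.85 points, past those 5 points by less than the wild-type SD of 3.97, so region width remains open. A promoter class that misses start sites also remains open: with H3K4me3-defined promoters the difference was −3.22 points, but because the wild-type gaps grew, while the 2-allele gaps, which such a class would have made smaller, grew too (to −27.0 and −26.0 points). Different calling of the 2-allele lists was not tested, and a need of distal regions for Arid1a, the biological explanation the design offers, stays open beside it.

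More cell cycle promoters were called with NICD than in wild type. With 18360 peaks in each of these lists, the log2 odds still differed by 0.79, and 16 and 13 members were called against 9 and 10. The excess over the 0.5 set beforehand was less than the NICD SD of 0.32, so longer NICD lists cannot be ruled out. Blood cells as the source remain open too: the mean number of haematopoietic promoters called differed by 1 at that length, under the 3 set beforehand, but at 1 and 2 against 1 and 0 of 30 the list was too near 0 to exclude them. More dividing cells under active Notch may be the reason, but no measure of cell division was analysed here.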

How the results depend on the processing

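Equal numbers with the 2-allele lists, the either-end and H3K4me3 promoters and the 200 bp peaks were chosen after seeing the data. The 2-allele lists hold no scores, so a stricter threshold and the planned equal numbers gave no value for them, and the exact p of 6 libraries cannot go below 0.0667. The group comparisons of the report kept their direction and their side of the threshold with autosomes only and with either gene end as the start, except for single genes: 6 gene patterns on the X chromosome, among them those of Vsig1, dropped out with autosomes only, and 2 weakened with either gene end (Bax in NICD against wild type and Irf2bp1 in 2-allele against NICD). Where a cause is not named below, the cause was not tested. What depth limits could not be compared over all groups, since the depth of the 2-allele libraries is unknown.

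With a −log10 q of at least 5 the exact p for peaks, covered length, promoter share and promoter genes was 0.0667 each, from fewer libraries. NICD against wild type then gave 127 regions on the wild-type side and 1282 and 13 genes, and 1-allele against NICD 0 genes on the 1-allele side. An unadjusted p below 0.05 was reached by 0 lists, the only possible outcome with 6 libraries. The floxed H3K4me3 list covered 1762 genes, and overlap with H3K4me3 was 62.8% in wild type and 26.6% in the 1-allele group.

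With 5165 peaks per list, 23 of the single-gene patterns held and 112 weakened, and the exact p was 0.0667 for covered length, 0.133 for promoter share and 0.0667 for promoter genes. Promoter share differed by 3.81 points (NICD against wild type) and −8.28 points (1-allele against NICD), both the reverse of the full lists. NICD against wild type gave 474 and 394 regions and 414 and 220 genes, and 1-allele against NICD 364 and 575 regions and 166 and 522 genes. Of the lists, 0 had an unadjusted p below 0.05, which 6 libraries cannot reach. Log2 odds differences turned to −0.16 (cell cycle, NICD against wild type) and, for 1-allele against NICD, to 1.13 (cell cycle), 0.074 (Notch), 0.026 (p53), 0.54 (gastric transcription factors) and −0.060 (inflammatory). Overlap with H3K4me3 was 89.7%, 98.6% and 41.6% in wild type, NICD and 1-allele.

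Adding the 2-allele lists by file order at 5165 peaks, 21 single-gene patterns held and 96 weakened, and promoter share differed by 11.2 points (2-allele against 1-allele) and promoter genes by 143.5 (2-allele against NICD), both reversed. The 2-allele against NICD counts were 348 and 368 regions, with 1.36% of all protein-coding genes on the 2-allele side and 256 genes on the other, and those against 1-allele 622 and 417 regions and 618 and 163 genes. Log2 odds for 2-allele against NICD turned to 1.15 (cell cycle), 0.051 (p53) and 0.79 (surface pit), 125 losses were shared and H3K4me3 overlap was 47.4%, above the 1-allele 41.6% and so the reverse order of the full lists. Of the lists, 6 passed the adjusted threshold, but each of the 6 differed by at most 1 gene between libraries and 3 had no member called, so these follow the count of other genes.

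With 14373 peaks per list and no 1-allele libraries, the exact p for promoter share was 0.0667 and NICD against wild type differed by 2.19 points, reversed. Regions and genes numbered 1354 and 713, and 524 and 129, for NICD against wild type, and 592 and 941 regions for 2-allele against NICD, with 0.845% of all protein-coding genes on the 2-allele side and 168 genes on the other. An unadjusted p below 0.05, which 6 libraries cannot reach, was found for 0 lists. The cell cycle odds of 2-allele against NICD turned to 0.076.

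A 2.5 kb window gave 13 genes on the 1-allele side against 2-allele and p53 odds of 0.11 (2-allele against NICD, reversed). With 50% of the region covered, the 1-allele gap was 0.31 points (reversed), NICD gained 9330 regions over wild type, and H3K4me3 overlap was 53.6%, 27.3% and 10.5% in wild type, 1-allele and 2-allele. Against housekeeping genes, Notch odds were 0.038 (1-allele against NICD) and p53 odds 0.27 (2-allele against NICD), both reversed. With 200 bp peaks, NICD against wild type gave 660 regions and 43 genes on the wild-type side, 1-allele against NICD 91 regions and 4 genes on the 1-allele side, 2-allele against NICD 210 regions on the 2-allele side and p53 odds of 0.12 (reversed), and 2-allele H3K4me3 overlap was 23.5%.

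With the replicate number as a block, promoter share and promoter genes had an exact p of 0.0833 each. Deviations of same-numbered libraries correlated between −0.03 and 0.10 over regions, which gives little sign that the numbers pair the libraries. These are deviations of called or not called values, which also follow list length, so a pairing cannot be excluded.

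Leaving out each library in turn, which lets more regions separate 2 groups by construction, gave these ranges. NICD against wild type gave 5933 to 22274 regions and 841 to 1720 genes on the NICD side and 248 to 2027 and 23 to 166 on the other. For 1-allele against NICD, 33 to 171 regions and 2 to 13 genes lay on the 1-allele side and 13341 to 32563 and 4098 to 6723 on the other. For 2-allele against NICD, 40 to 423 regions and 0.0274% to 0.480% of all protein-coding genes lay on the 2-allele side and 7067 to 24964 regions and 821 to 1839 genes on the other. For 2-allele against 1-allele, 4193 to 6969 and 2621 to 5068 lay on the 2-allele side and 167 to 523 and 8 to 81 on the other. Shared losses ranged from 6656 to 24464 and lists with an unadjusted p below 0.05 from 1 to 9. The exact p for promoter share ranged from 0.0286 to 0.0762, its difference between 2-allele and 1-allele from −5.27 to 1.27 points, and the 1-allele gap from −5.45 to 1.38 points. Mean retention ranged from 37.4% to 63.3% in wild type, 14.1% to 31.6% in the 1-allele and 33.4% to 60.5% in the 2-allele group, and the gap from −14.1 to −6.30 points in wild type and −27.7 to −14.4 points in the 2-allele group. Log2 odds for 2-allele against NICD ranged from −1.27 to −0.063 (cell cycle), −1.01 to −0.30 (Notch), −0.12 to −0.034 (p53) and −3.34 to −0.88 (surface pit). For NICD against wild type they ranged from 1.03 to 2.24 (cell cycle) and 0.49 to 1.20 (Notch), and for 1-allele against NICD from −1.20 to −0.50 (Notch), −1.35 to −0.67 (p53) and 0.43 to 1.05 (inflammatory).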

Other observations

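The test of the hypothesis here was set down before its result was seen, and the equal-length counts were chosen after the data had been seen.

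With 14373 peaks in each wild-type, NICD and 2-allele list, surface pit cell promoters were called in 9 and 10 of 14 cases in wild type, 5 and 5 in NICD and 6 and 4 in the 2-allele libraries. Genes of the p53 pathway numbered 20 and 19 of 30 in wild type, 27 and 23 in NICD and 25 and 25 in the 2-allele libraries. Mucous neck cell promoters were called in 1 and 2 of 9 cases in wild type, 4 and 4 in NICD and 3 and 3 in the 2-allele libraries, and metaplasia genes in 6 and 5 of 16 in wild type, 8 and 7 in NICD and 7 and 7 in the 2-allele libraries. For both of these lists the exact permutation p was 0.0667 (adjusted 0.360, n = 2 per group), the smallest that 6 libraries allow, which 5 of the 27 lists reached. For surface pit and p53 genes the exact p was 0.20 (adjusted 0.491). Notch pathway genes were called in 15 and 16 of 30 cases in wild type and 17 and 17 in NICD.

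Among the 5165 strongest peaks of each list, surface pit promoters were called in 6 and 2 cases with 1 floxed allele, 1 and 0 in NICD, 2 and 3 in wild type and 1 and 1 in the 2-allele libraries (exact permutation p = 0.124, adjusted 0.400, n = 2 per group). Foxq1 was called in both 1-allele libraries and both wild-type libraries there, and Klf4, a factor of differentiated epithelium, in both 1-allele and both 2-allele libraries; both were chosen after their values were seen.

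Promoters of 1657 protein-coding genes carried a peak in all 11 libraries, and 7703 genes in none. Mitochondrial peaks numbered 6 and 5 in wild type, 6 and 1 in NICD, 4 and 3 in the 1-allele and 0 and 0 in the 2-allele H3K27ac lists.

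A hypothesis was that regions gained with NICD need Arid1a. At equal NICD strength, the 6070 NICD regions called in no wild-type library were retained less often than the 11332 called in both, in each floxed library (−8.17 and −12.3 points with 1 allele, −21.6 and −14.3 with 2). Read the other way, regions called in neither 2-allele library differed from those in both by −19.1 and −22.2 points in wild type, which is the same association and tests no cause. Regions called in more libraries may be easier to call anywhere, and no value here separates that from the hypothesis, which therefore stays open.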
